A study of Mus musculus with 6 samples.

How the data were processed

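Total RNA of mouse bone marrow-derived dendritic cells was profiled by multiplex small RNA sequencing (MSR-seq), in which barcoded libraries are reverse transcribed on a solid support and sequenced together. Per the labels, bone marrow cells of C57BL/6 mice were grown with GM-CSF at 15 ng/mL in medium with 10% dialyzed serum, without queuine (0Q) or with 100 nM queuine (100Q), were fed on days 2 and 4 and were harvested on day 5. The cells were plated in triplicate, so the p-values measure the spread between those 3 samples per group and not between animals.

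The deposited abundance tables hold the count of reads per reference sequence, with no normalization, per the file headers. The deposited position tables hold counts of reads that cover each position of each reference and counts of each base, deletion and insertion there, per the file headers. Per the file headers, the same tables give the mutation value, a fraction that the authors computed as reads with another base over the reads covering the position. A further deposited column gives stops as another kind of value, the drop in coverage from the next position on the 3′ side over the coverage of that position, per the file headers. Per the labels, the authors made these values by quality control, demultiplexing and alignment to mm39 tRNA genes, with SAMtools and custom Python and R scripts. The aligner, its version, the handling of reads that match several references and any read filters were not given in the sources used here. The base, deletion and insertion counts added up to the coverage at 112915 of 112915 positions, and the deposited mutation fraction matched the recomputed one at 112075 of 112075 covered positions within 0.0001.

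The fractions used here were recomputed from the counts, and stops were set to 0 where coverage rose toward the 5′ end. Position 34 was found as the anticodon triplet named by the reference, preceded by T, within positions 30 to 40 (228 tRNA references). For 9 references it was found within positions 25 to 42, preceded by T or C, a rule added after the files were seen. Canonical positions were counted from it, so positions far from the anticodon can differ from the standard numbering where the D loop or variable loop differs in length. Counts were summed over the references of each anticodon family, giving 51 cytosolic and 22 mitochondrial families, since 162 tRNA references lay within 3 substitutions of another and can share reads. References were placed on GRCm39 with BLAST+ 2.17.0 and exact matching, and annotated with GENCODE.

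Abundance was tested in edgeR 4.0.16 (TMM normalization, quasi-likelihood F test) on families and on references with a mean of at least 10 counts, and given as CPM on the TMM scale. Mismatches, deletions, insertions and stops were each tested with a quasi-binomial model of changed against unchanged reads per position, with dispersions moderated along coverage by limma 3.58.1. A tested position had at least 100 reads in every library and, by reference, a mean changed share of at least 0.01. Adjusted p-values are Benjamini-Hochberg over all families, references or positions of a readout, and a feature passed at an adjusted p below 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and with fry in limma, on log2 CPM with a prior count of 2. Shares were compared by the two-sided exact permutation test in scipy 1.17.1, whose smallest p for 3 against 3 is 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and matplotlib 3.10.9 were also used.

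The tests, thresholds, gene lists, position lists, named-gene rule and most alternatives were chosen before the data were examined. By that rule the text names the 8 queuosine families, iMet-CAT and SeC-TCA, and up to 10 families that rose and 10 that fell with the largest log2 fold changes among those past the threshold whose groups did not overlap. By reference it names up to 3 each way. For mismatches it names position 34 of the queuosine families and up to 10 positions each way by the difference in mean share, 1 per family and position, and for deletions, insertions and stops up to 5 each way. The examples given for families at position 26, for neighbours of position 34 and for the position lists were chosen after their values were seen. The alternatives were DESeq2 1.42.0, its size factors, total count and cytosolic scaling, other count, coverage and share minimums, limma on log2 odds, unweighted family means, all kinds of change together, a replicate block, barcode as a term, and leaving out each library. Alternatives chosen after seeing the data were a dispersion without a trend, the share of reads outside tRNA as a term, position 9 counted from the 5′ end, and those for deletions, insertions and stops.

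Total counts ran from 12389146 to 17858949 reads per library, and the reads have no molecular identifiers in the deposited tables, so floors and coverage speak of counting error only. The abundance test and the mismatch test were tested on simulated data drawn from the real means and library sizes. Among 72 families with 12 changed, edgeR recovered 8.33% at a fold of 1.25, 66.7% at 1.5 and 83.3% at 2, and among 219 references with 40 changed it recovered 2.50%, 62.5% and 92.5%. Among 2209 positions with 200 changed, the quasi-binomial model recovered 19.5%, 52.5% and 76.5% at odds ratios of 1.25, 1.5 and 2, and called 0.299%, 0.398% and 0.647% of unchanged positions. The 7 references other than tRNA were left out of the tests and used for shares only.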

Results

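Transfer RNA was sequenced from mouse bone marrow-derived dendritic cells grown without queuine or with 100 nM queuine. Queuine is the base that mammalian cells take up and insert into tRNA as queuosine, a hypermodified guanosine. Queuosine sits at position 34, the first base of the anticodon, in the tRNAs for tyrosine, histidine, asparagine and aspartate of the cytosol and of mitochondria. The 6 libraries formed 2 groups of 3, called 0Q and 100Q by the labels, and the cells were harvested on day 5 of culture. Total counts in 0Q replicates 1 to 3 were 17551803, 17858949 and 12389146 reads, and those in 100Q replicates 1 to 3 were 16038170, 15814319 and 13012736 reads. Reads were assigned to 244 reference sequences, of which 215 were cytosolic tRNAs, 22 were mitochondrial tRNAs and 7 were other small RNAs. Lys-CTT was the most abundant anticodon family in each of the 6 libraries, with 8.50% of tRNA reads in 0Q replicate 1 and 8.20% in 100Q replicate 3. All 0Q libraries came from 1 library pool and all 100Q libraries from the other, so pool and group cannot be told apart. The ligation barcodes 6 and 7 occurred in both groups and gave the within-barcode values below. Percentages are means ± SD over n = 3 libraries per group unless stated otherwise.

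Queuine-fed cells had more misread bases at position 34 of the tRNAs that carry queuosine, in a comparison that addresses the series' question of how the modification affects tRNAs of both compartments. The share of mismatched reads there rose in 5 of the 8 families and had a higher mean in 8 of 8. It rose in Asn-GTT from 0.611% ± 0.111 to 2.01% ± 0.577, and in His-GTG from 0.457% ± 0.114 to 1.54% ± 0.248. In mitochondria it rose in mt-His-GTG from 0.821% ± 0.195 to 3.56% ± 0.607, in mt-Asp-GTC from 2.82% ± 0.374 to 7.84% ± 1.27, and in mt-Tyr-GTA from 0.742% ± 0.129 to 1.66% ± 0.0804. Cytosolic Asp-GTC and Tyr-GTA, whose queuosine carries a further sugar in mammals, did not pass the test, with 6.94% ± 1.24 against 8.93% ± 1.18 and 1.45% ± 0.292 against 1.64% ± 0.222. The third family that did not pass was mt-Asn-GTT, with 1.00% ± 0.842 against 1.66% ± 0.394 at a coverage of only 321 to 552 reads.

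The log2 odds ratio of a mismatch at position 34 was 2.20 ± 0.23 (SE) in mt-His-GTG (adjusted p = 0.00219), 1.82 ± 0.22 in His-GTG (0.00355) and 1.20 ± 0.14 in mt-Tyr-GTA (0.0041). It was 1.58 ± 0.23 in mt-Asp-GTC (0.00917) and 1.74 ± 0.31 in Asn-GTT (0.0154). Adjusted over the list alone, 5 of the 8 families also passed. Asp-GTC had a log2 odds ratio of 0.42 ± 0.17 with an adjusted p of 0.144, Tyr-GTA had 0.22 ± 0.17 with 0.413, and mt-Asn-GTT had 0.91 ± 0.64 with 0.361. The two-sided exact permutation test, which cannot go below 0.1 with this design, gave 0.1 for the 5 families that passed and for Asp-GTC, 0.4 for Tyr-GTA and 0.3 for mt-Asn-GTT. Within barcodes 6 and 7 the difference was 2.30 and 3.18 points in mt-His-GTG, 0.947 and 1.23 points in His-GTG, 1.04 and 1.93 points in Asn-GTT, 6.15 and 3.14 points in mt-Asp-GTC, and 0.973 and 0.872 points in mt-Tyr-GTA. Position 34 was covered by 364799 to 513532 reads in Asn-GTT, 139153 to 286987 in His-GTG, 7888 to 16650 in mt-His-GTG, 4338 to 8561 in mt-Tyr-GTA and 480 to 1077 in mt-Asp-GTC. Asn-GTT lost its call without 0Q replicate 1 (adjusted p = 0.0587), without 0Q replicate 2 (0.0787) and without 100Q replicate 3 (0.0537), and an unweighted mean over references ended the calls of Asn-GTT and His-GTG (0.246 for each) at log2 odds ratios of 2.42 and 1.78. With the share of reads outside tRNA as a term, chosen after seeing the data, mt-Asp-GTC did not pass (1.56, 0.0625).

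**Figure D1:**
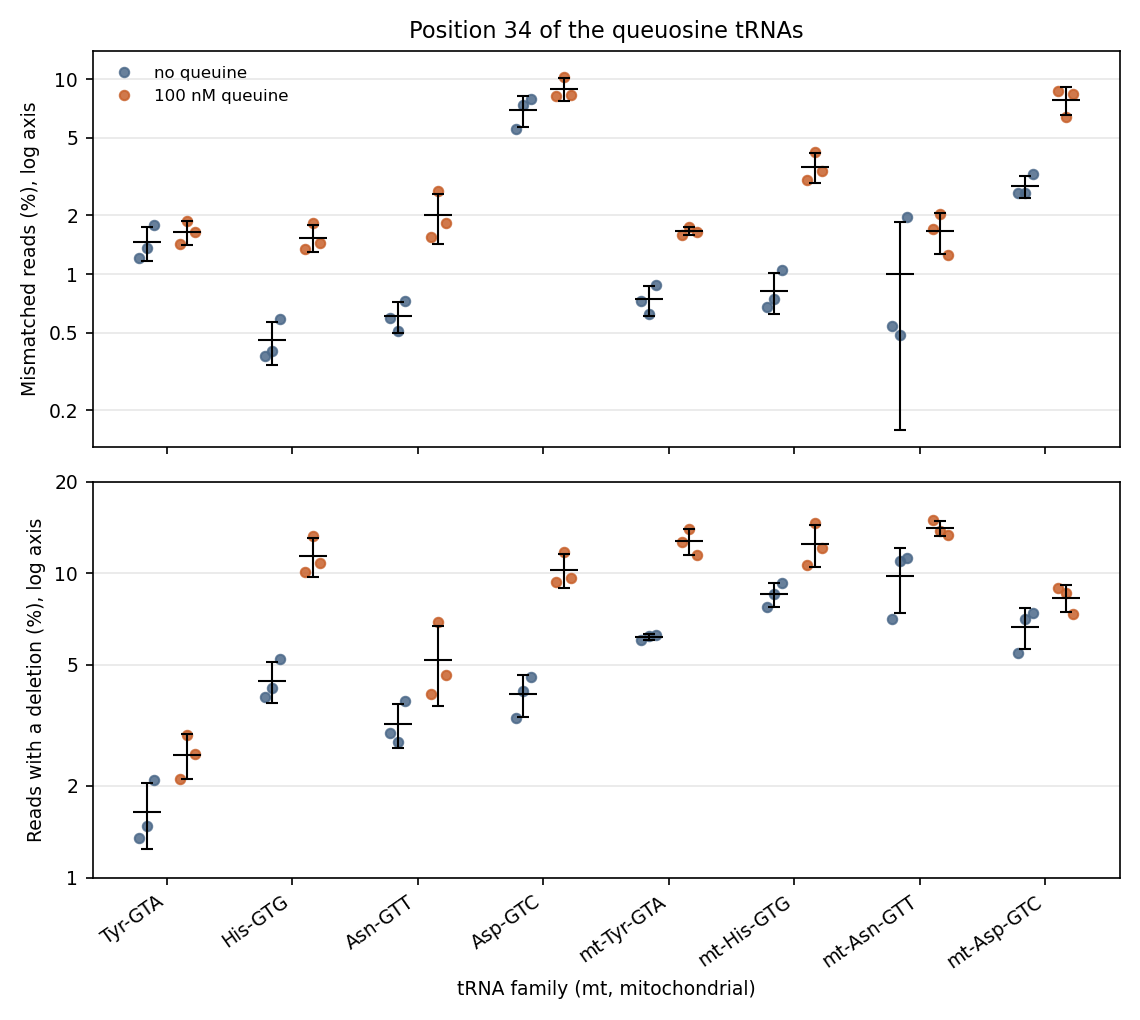
Percent of reads with a mismatch and with a deletion at position 34 of the 8 queuosine tRNA families, on log axes. Points are libraries and bars are mean ± SD of 3 libraries, and the 100Q mean lies above the 0Q mean in 8 of 8 families for each readout.

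Deletions, insertions and stops of the reverse transcriptase at position 34 differed among the queuosine tRNAs as well. Deletions rose in Asp-GTC from 4.00% ± 0.620 to 10.3% ± 1.29 (adjusted p = 0.00285), in His-GTG from 4.44% ± 0.681 to 11.4% ± 1.64 (0.00501) and in mt-Tyr-GTA from 6.17% ± 0.127 to 12.7% ± 1.3 (0.0015). They had a higher mean in the other 5 families without passing the test, as in Tyr-GTA with 1.64% ± 0.402 against 2.54% ± 0.420 (0.147), and adjusted over the list alone 7 of 8 passed. Insertions rose in Asn-GTT from 0.121% ± 0.0178 to 0.80% ± 0.240 (1.15e-06), with smaller rises in His-GTG and Tyr-GTA. In Asn-GTT, stops at position 34 fell from 0.454% ± 0.0755 to 0.0220% ± 0.00453 (0.00026), and those at position 33 rose from 0.192% ± 0.0255 to 0.835% ± 0.240 (0.0143). Mismatches, deletions and insertions together rose in Asp-GTC from 11% ± 1.86 to 19.2% ± 2.48 (0.0185), while Asn-GTT with 3.93% ± 0.660 against 8.00% ± 2.35 did not pass (0.0644). Within barcodes 6 and 7 the deletion difference was 5.30 and 7.17 points in Asp-GTC, 5.92 and 8.02 points in His-GTG, and 6.42 and 7.76 points in mt-Tyr-GTA.

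Some neighbouring bases of the anticodon loop changed as well. In Tyr-GTA, mismatches at position 36 rose from 0.0812% ± 0.00782 to 0.531% ± 0.0391 (adjusted p = 6.6e-05), and deletions at position 37 rose from 1.18% ± 0.0774 to 2.98% ± 0.152 (0.000453). In His-GTG, deletions at position 36 rose from 0.911% ± 0.144 to 3.38% ± 0.238 (0.000533) and those at position 33 from 4.02% ± 0.642 to 9.26% ± 1.34 (0.00733). In mt-Tyr-GTA, deletions at position 37 rose from 0.396% ± 0.0476 to 1.56% ± 0.335 (0.00669). Position 32 moved in opposite directions in Asn-GTT, where mismatches rose from 0.0659% ± 0.00886 to 0.229% ± 0.0129 (0.000261), and in Asp-GTC, where they fell from 0.319% ± 0.00588 to 0.126% ± 0.00738 (8.4e-05). Of the 44 family positions 32, 33 and 35 to 38 of the queuosine tRNAs, 7 rose, 3 fell and 34 did not pass for mismatches, with a median difference of 0.0393 points. Adjusted over the list alone, 9 rose and 3 fell. By reference sequence, 2 of 11 such positions rose and 9 did not pass, against 3 that rose and 1 that fell adjusted over the list alone, 4 with an unadjusted p under 0.05, and 0 by limma.

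**Figure D2:**
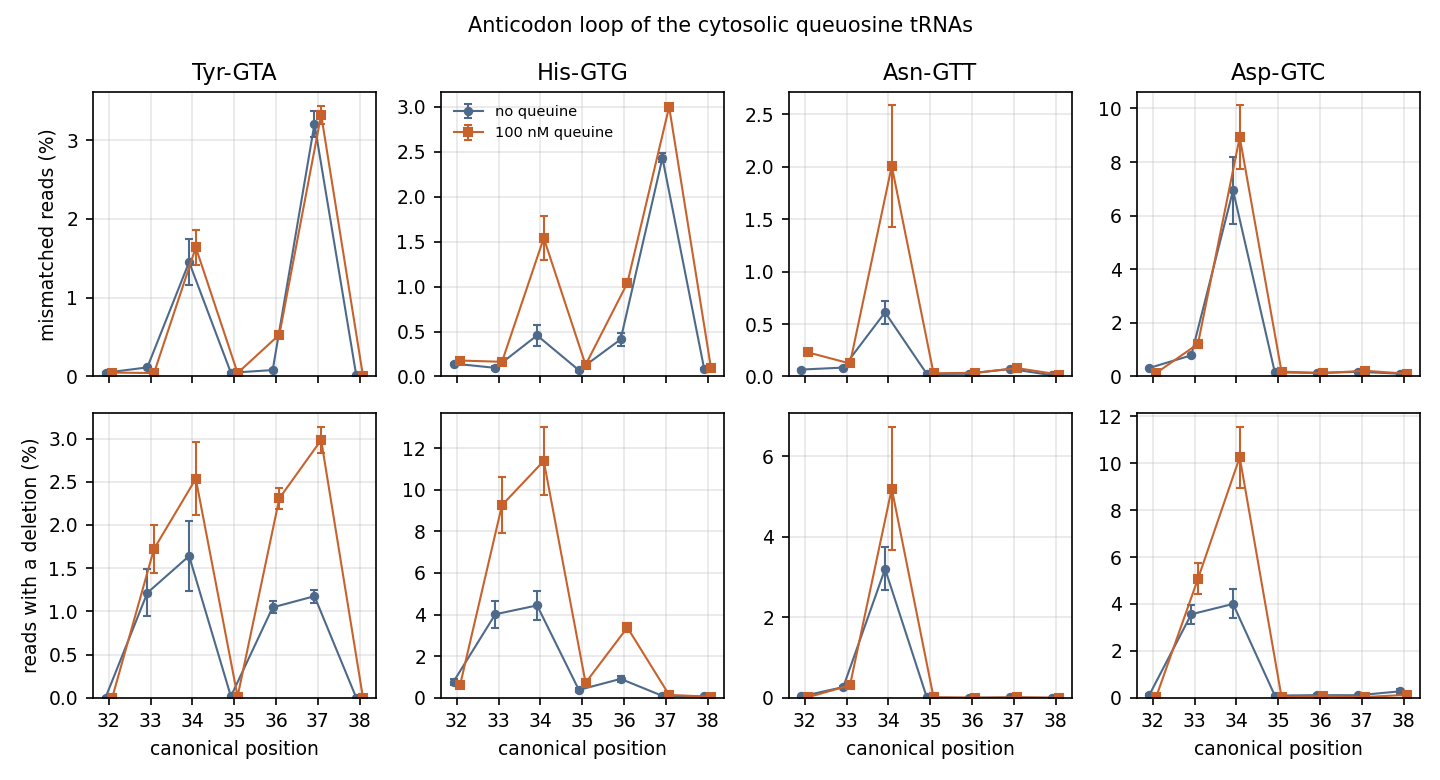
Percent of reads with a mismatch and with a deletion at positions 32 to 38 of the 4 cytosolic queuosine tRNA families in 0Q and 100Q, as mean ± SD of 3 libraries. Beyond position 34, the groups separate at position 36 of Tyr-GTA, with 0.0812% against 0.531% mismatches, and at positions 33 and 36 of His-GTG for deletions.

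The tRNAs with guanosine but no queuosine at position 34 served as the comparison for the queuosine families. With the quasi-binomial model 0 of 18 such reference positions passed, adjusted over all positions or over the list alone, 6 had an unadjusted p under 0.05, and limma called 0. Their median difference was 0.925 points. Summed by family, the largest log2 odds ratio was that of Cys-GCA, with 2.54% ± 0.570 against 3.44% ± 0.427 (0.49 ± 0.17, unadjusted p = 0.0284, adjusted p = 0.111). Ser-GCT had 6.26% ± 1.49 against 8.00% ± 1.48 (adjusted p = 0.236), Gly-GCC had 8.60% ± 2.30 against 8.50% ± 1.24 (0.960), and Phe-GAA had 3.23% ± 0.578 against 2.56% ± 0.308 (0.216). By reference sequence, mismatches at position 34 rose in 7 of 15 queuosine tRNA references and fell in 0, and the count was the same adjusted over the list alone. Of the 15, 9 had an unadjusted p under 0.05, and limma called 6 higher and 0 lower. The median difference of the 15 was 1.12 points, not far above the 0.925 points of the 18 comparison references. These differences start from unlike shares, with a median of 1.04% in 0Q for the 15 and 4.22% for the 18. The median log2 odds ratio was 0.91 for the 15 and 0.43 for the 18.

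At other modified positions mismatches changed in small groups of tRNAs. Of all 2209 positions tested for mismatches 143 passed. The shares at adenosine 58, at position 37 and at position 9 counted from the 5′ end were near or below that. At position 34 of the tRNAs with adenosine there, which is deaminated to inosine, mismatches fell in 3 of 31 references, all of Thr-AGT, as from 98.6% ± 0.213 to 97.6% ± 0.266 in Thr-AGT-1-1. At position 32, where threonine tRNAs carry 3-methylcytidine, they fell in 5 of 33 references of serine, threonine and arginine tRNAs. All 5 were threonine tRNAs: Thr-TGT-1-1, from 73.1% ± 0.542 to 69.7% ± 0.811, and Thr-AGT references, which included the 3 that fell at inosine. At adenosine 58, the site of 1-methyladenosine, they rose in 9 of 150 references and fell in 2, with a rise from 69.7% ± 0.738 to 80.3% ± 0.523 in Arg-ACG-3-1 and a fall from 81.0% ± 1.07 to 78.7% ± 0.377 in Arg-TCG-1-1. The other fall, in Gln-CTG-1-1, went with a rise of deletions at the same base from 33.8% ± 0.923 to 41.7% ± 1.08. For position 9, the site of 1-methylpurines, counting back from position 34 gave 10 falls and 5 rises among 74 references. The falls lay at base 10 of 9 leucine tRNA references, such as Leu-AAG-2-1 (5.24% ± 0.344 to 4.09% ± 0.0552), and at base 6 of mt-Thr-TGT, so none of them is shown to be at the methylated site. Counted from the 5′ end instead, an alternative chosen after seeing the data, 5 of 115 rose and 0 fell with the quasi-binomial model, and 19 had an unadjusted p under 0.05. By limma 0 rose and 1 fell of the inosine positions, 0 rose and 4 fell at position 32, 4 rose and 0 fell at adenosine 58, and for position 9 it called 1 higher and 1 lower counted from position 34 and 1 higher and 0 lower counted from the 5′ end. Of 84 purines at position 37, 3 rose, as in Leu-CAA-2-1 from 23.3% ± 0.215 to 25.1% ± 0.315. Adjusted over the list alone, 4 inosine positions fell, 6 at position 32 fell, 9 at adenosine 58 rose and 2 fell, 8 at position 9 rose and 12 fell. At position 37, 0 passed over the list alone, 10 had an unadjusted p under 0.05, and limma called 0. The median differences were -0.0812 points for inosine, 0.121 for position 32, -0.0778 for adenosine 58, 0.119 for position 9 and 0.0869 for position 37.

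Across whole tRNAs, mismatches rose far more often than they fell in queuine-fed cells, and the rises gathered at position 26. Of 2209 positions tested by reference, 143 passed, 120 higher and 23 lower. Guanosine 26, the site of dimethylguanosine at the hinge between the D and anticodon arms, rose in 39 of 104 references and fell in 0, against 54 and 1 adjusted over the list alone, with a median difference of 1.10 points. Of the 104, 60 had an unadjusted p under 0.05, and limma called 32 higher and 0 lower. Examples, with positions counted from the 5′ end of each reference, were Trp-CCA-2-1 position 25 (22.5% ± 0.765 to 34% ± 0.274), Arg-TCG-3-1 position 26 (38.2% ± 0.149 to 49.2% ± 0.374), Met-CAT-2-1 position 26 (41.7% ± 0.319 to 50.6% ± 1.21), Ile-TAT-1-1 position 27 (28.8% ± 0.225 to 37.1% ± 0.891) and Phe-GAA-1-1 position 26 (71.8% ± 0.382 to 80.0% ± 0.358). The largest rise among the named positions was that of Met-CAT-5-1 position 24, from 19.6% ± 2.38 to 36% ± 3.02, with 20.1 and 15.6 points within barcodes 6 and 7. Ala-TGC-6-1 position 59 rose from 33.3% ± 3.38 to 48.4% ± 5.56 at a coverage of 116 to 266 reads, and Met-CAT-6-1 rose at positions 56 (18.7% ± 2.20 to 28.9% ± 2.44) and 58 (23.8% ± 1.82 to 32.6% ± 2.79). At position 58 of Met-CAT-6-1 deletions fell from 74.4% ± 2.05 to 64.3% ± 2.90, on 1266 to 1725 reads. The mismatch rise there thus went with a fall of deletions, and most reads differed from the reference in both groups. The falls of mismatches were smaller and included mt-Thr-TGT position 6 (32.2% ± 0.685 to 28.7% ± 0.297), Gln-CTG-1-1 position 57 (53.1% ± 0.658 to 49.6% ± 1.03), Ser-GCT-3-1 position 6 (22.2% ± 0.597 to 19.6% ± 0.577), Asn-GTT-3-1 position 21 (17.7% ± 0.281 to 15.8% ± 0.204), Leu-TAG-2-1 position 10 (5.46% ± 0.233 to 4.48% ± 0.134) and Thr-AGT-1-1 position 33 (89.7% ± 0.438 to 86.9% ± 0.549). At position 57 of Gln-CTG-1-1 deletions rose by more (7.88 points) than mismatches changed (-3.54 points), so misreading of this base did not become rarer. The number of positions past the threshold was 292 without 0Q replicate 3, 81 without 0Q replicate 1, 79 without 0Q replicate 2, 81 without 100Q replicate 1, 81 without 100Q replicate 2 and 74 without 100Q replicate 3. Of the 46 positions named by rule in all readouts, 28 lost their call in at least 1 alternative, 19 of them without 0Q replicate 1, 19 without 0Q replicate 2, 3 without 0Q replicate 3, 14 without 100Q replicate 1, 14 without 100Q replicate 2 and 15 without 100Q replicate 3.

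Reverse transcription stopped less often at position 26 in libraries of queuine-fed cells, mostly in tRNAs that do not carry queuosine. Of 67 families with this position, stops fell in 26 and rose in 0. Among these 26, selected for their fall, the median change of stops was -34.1%. The mean mismatch share there was higher in 26 of the 26, in 18 of them past the test. With the quasi-binomial model 0 families had more stops at an unadjusted p under 0.05, and by reference limma called 81 lower and 0 higher. In Met-CAT stops fell from 37.3% ± 0.981 to 20.1% ± 1.05 while mismatches rose from 46.7% ± 0.0768 to 52.4% ± 1.47. In Phe-GAA stops fell from 24.8% ± 0.266 to 12.7% ± 0.223 while mismatches rose from 71.7% ± 0.382 to 79.7% ± 0.304. Trp-CCA went from 66.9% ± 0.128 to 57.4% ± 0.320 stops and from 33.1% ± 0.297 to 42.3% ± 0.165 mismatches. In Tyr-GTA, the only queuosine family among the 26, stops fell from 38.8% ± 0.728 to 27.6% ± 0.457, and its mismatches were 13.7% ± 0.174 against 14.1% ± 0.396 (adjusted p = 0.256). The share of cytosolic coverage that reached position 5 was 65.1% ± 1.28 in 0Q and 68.9% ± 1.20 in 100Q (exact permutation p = 0.1), and 4.32 and 4.87 points higher within barcodes 6 and 7.

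**Figure D3:**
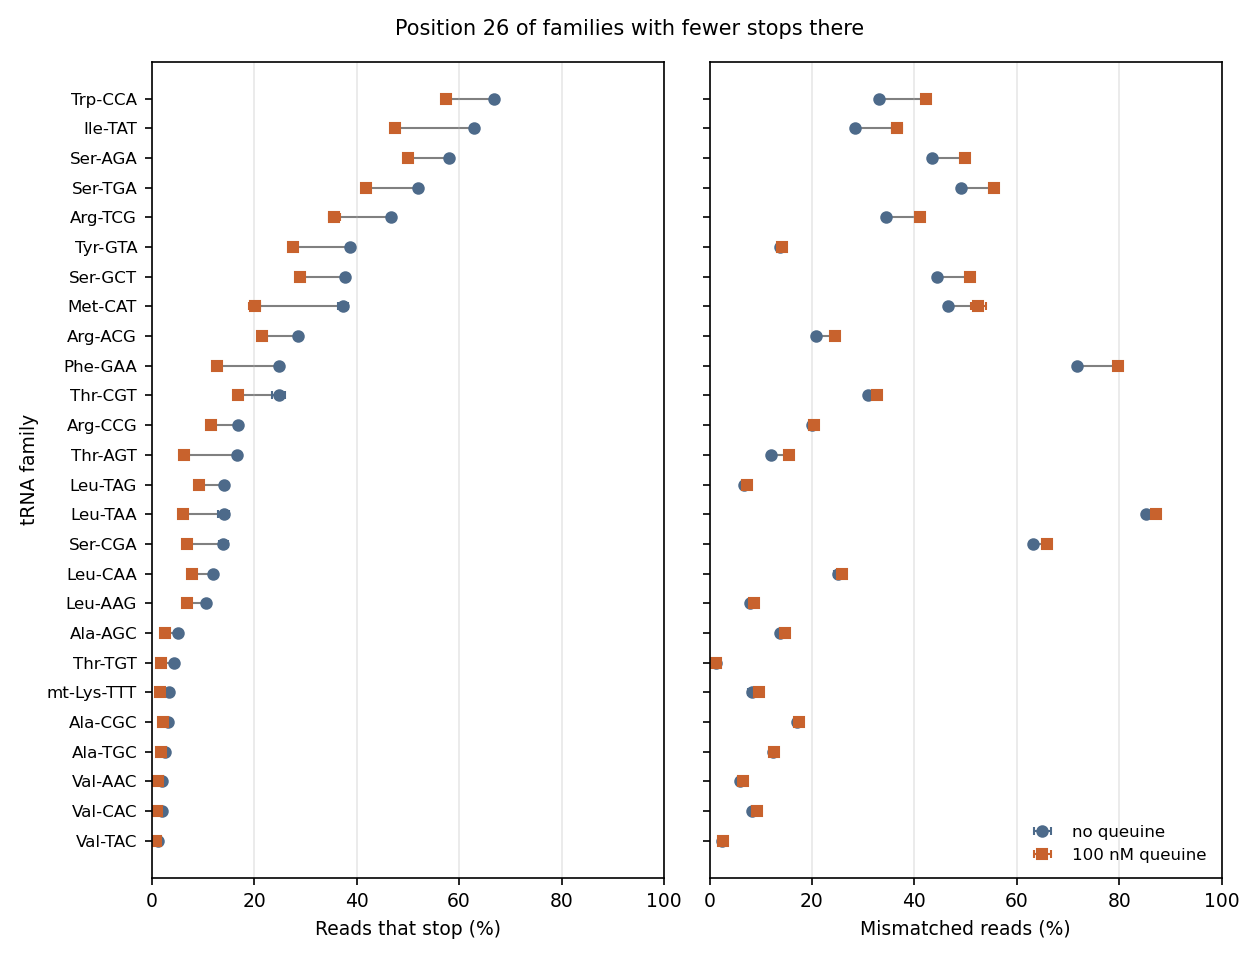
Percent of stops and of mismatches at position 26 in the 26 families with fewer stops, as mean ± SD of 3 libraries per group. Stops are lower and mismatches have a higher mean in 100Q in 26 of 26 families.

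Over all positions and readouts, changed reads were mostly more frequent and stops mostly less frequent in 100Q. Of 1561 positions tested for stops, 275 fell and 33 rose, with 82 of the falls at canonical position 26, 61 at the adjacent position 25 and 31 at position 24. In the examples that follow, positions are counted from the 5′ end of each reference. Examples were Thr-AGT-5-1 position 27 (42% ± 0.901 to 18.0% ± 2.08), Met-CAT-4-1 position 26 (41.6% ± 1.94 to 20.7% ± 2.28), Thr-CGT-3-1 position 27 (29.0% ± 1.00 to 11.8% ± 0.838), Thr-TGT-1-1 position 27 (32.5% ± 0.282 to 15.7% ± 0.442) and Ser-GGA-1-1 position 13 (22.4% ± 3.83 to 6.13% ± 4.77). Stops rose at Val-CAC-4-1 position 11 (11.3% ± 2.26 to 25.2% ± 5.52), Asn-GTT-1-1 position 7 (31.5% ± 2.30 to 39.2% ± 1.84), Asn-GTT-3-1 position 3 (20.8% ± 0.914 to 25.4% ± 0.671), Trp-CCA-4-1 position 9 (9.05% ± 0.614 to 13.6% ± 0.616) and position 1 of mt-Ala-TGC (9.93% ± 1.07 to 13.1% ± 0.408). Of 2168 positions tested for deletions, 202 rose and 13 fell, 180 of the 215 in tRNAs without queuosine. Deletions rose in Gln-CTG-1-1 at positions 56 (36.3% ± 0.925 to 44.1% ± 0.985) and 57 (33.8% ± 0.923 to 41.7% ± 1.08) and in Cys-GCA-5-1 at position 17 (24.6% ± 1.92 to 31.5% ± 1.82). They fell in Met-CAT-6-1 at positions 57 (77.6% ± 1.96 to 67.4% ± 2.22) and 58 (74.4% ± 2.05 to 64.3% ± 2.90), of which 58 had more mismatches in 100Q. Deletions also fell in Leu-CAG-4-1 at positions 26 (29.9% ± 2.30 to 23.5% ± 1.20, canonical position 25) and 27 (32.1% ± 2.66 to 25.5% ± 1.58, canonical position 26). In mt-Lys-TTT they fell at position 26 (41.9% ± 0.407 to 37.0% ± 0.915), which is canonical position 33. Of 79 positions tested for insertions, 10 rose, as in Thr-TGT-1-1 position 19 (7.53% ± 0.457 to 10.2% ± 0.709), Thr-AGT-3-1 position 7 (1.31% ± 0.816 to 3.27% ± 0.136) and Tyr-GTA-1-1 position 26 (1.33% ± 0.132 to 2.26% ± 0.0906), and 1 fell, Lys-TTT-2-1 position 32 (1.31% ± 0.0372 to 0.780% ± 0.137). Limma on log2 odds called 65 deletions, and 105 passed with the share of reads outside tRNA as a term, both chosen after seeing the data. The count for deletions was 663 without 0Q replicate 3, 64 without 0Q replicate 1, 57 without 0Q replicate 2, 53 without 100Q replicate 1, 54 without 100Q replicate 2 and 44 without 100Q replicate 3. The count for insertions was 5 without 0Q replicate 1, 2 without 0Q replicate 2 and 7 without 100Q replicate 3.

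In abundance, the queuosine tRNAs of the cytosol parted: those for aspartate and tyrosine fell, that for histidine rose and that for asparagine did not pass the test. Asp-GTC fell by 28.8%, from 44366 ± 771 to 31606 ± 1121 CPM (log2 fold change -0.49 ± 0.08 SE, adjusted p = 0.00168), and Tyr-GTA fell by 26.2%, from 34353 ± 2532 to 25339 ± 361 (-0.44 ± 0.09, 0.00462). His-GTG rose from 13163 ± 1768 to 18118 ± 2918 CPM (0.46 ± 0.13, 0.0478), with overlapping groups. Glutamine tRNAs rose, Gln-TTG from 3802 ± 168 to 5783 ± 903 (0.60 ± 0.12, 0.00462) and Gln-CTG from 13673 ± 851 to 19854 ± 337 (0.54 ± 0.09, 0.00168), as did Ser-CGA from 4551 ± 571 to 6036 ± 453 (0.41 ± 0.12, 0.0478). Of 72 families, 4 rose and 2 fell, with 25 at an unadjusted p under 0.05. Asn-GTT had a log2 fold change of 0.09 ± 0.12 (0.575), and -0.03 when scaled to cytosolic tRNAs. The mitochondrial families did not pass, with -0.33 ± 0.20 for mt-Tyr-GTA (0.25), -0.29 ± 0.21 for mt-His-GTG (0.298), -0.11 ± 0.23 for mt-Asn-GTT (0.707) and -0.51 ± 0.25 for mt-Asp-GTC (0.148). Initiator iMet-CAT had -0.18 ± 0.20 (0.521), and -0.55 with an adjusted p of 0.000798 without 100Q replicate 2, and selenocysteine SeC-TCA had -0.05 ± 0.12 (0.758). Within barcodes 6 and 7 the log2 ratios were -0.47 and -0.54 for Asp-GTC, -0.56 and -0.39 for Tyr-GTA, 0.49 and 0.78 for Gln-TTG, 0.45 and 0.60 for Gln-CTG, 0.28 and 0.31 for Ser-CGA and 0.37 and 0.33 for His-GTG.

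Of the abundance changes by family, those of Asp-GTC, Tyr-GTA and Gln-CTG passed under each of 4 scalings, Gln-TTG under 2, and His-GTG and Ser-CGA under 1. Asp-GTC ranged from -0.60 to -0.49 and Tyr-GTA from -0.55 to -0.44. The median log2 fold change of all families was -0.02, and -0.10 with total count scaling and -0.14 with cytosolic scaling, under each of which 1 family rose and 3 fell. Only barcodes 6 and 7 occurred in both groups, so a fit with barcode as a term compares the groups within those alone. With 4 barcodes among 6 libraries it leaves 1 residual degree of freedom, so its counts of calls are uncertain in both directions. By reference sequence the same fit called 47, against 18 in the main test. With barcode as a term in edgeR, 0 families passed and 28 had an unadjusted p under 0.05, and the adjusted p was 0.0912 for each of the 6 called families. Their log2 fold changes were then -0.50 for Asp-GTC, -0.48 for Tyr-GTA, 0.63 for Gln-TTG, 0.52 for Gln-CTG, 0.35 for His-GTG and 0.30 for Ser-CGA. With the share of reads outside tRNA as a term, chosen after seeing the data, His-GTG (0.25, adjusted p = 0.924), Ser-CGA (0.25, 0.924) and Gln-CTG (0.45, 0.0796) did not pass. The number of families was 3 without 0Q replicate 1, 18 without 0Q replicate 2 and 36 without 100Q replicate 2. Gln-TTG lost its call without 0Q replicate 1 (adjusted p = 0.09), and His-GTG lost it without 0Q replicate 1 (0.26) and without 0Q replicate 3 (0.0819). Ser-CGA lost it without 0Q replicate 1 (0.259), 0Q replicate 3 (0.129), 100Q replicate 1 (0.181) and 100Q replicate 3 (0.0677).

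**Figure D4:**
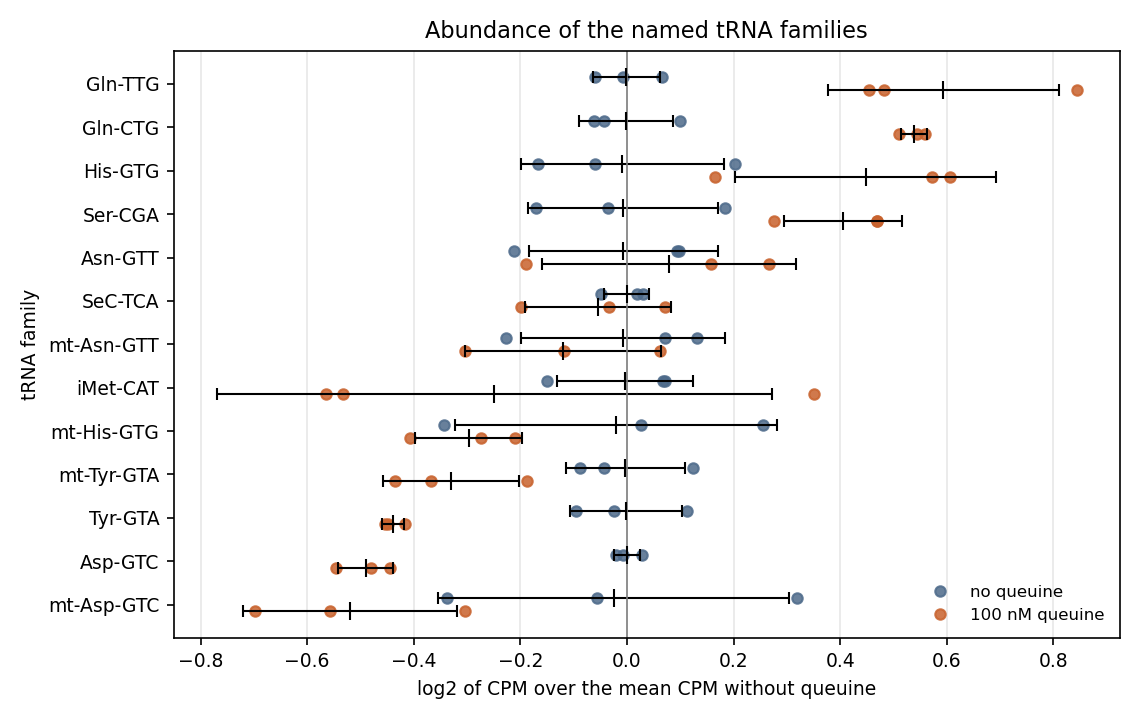
Log2 of CPM over the mean of the 0Q libraries for the 13 named tRNA families. Points are libraries, and the 3 points of 100Q lie below those of 0Q for Asp-GTC and Tyr-GTA and above them for Gln-TTG, Gln-CTG and Ser-CGA.

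By reference sequence, the falls were those of 2 Asp-GTC, 4 Tyr-GTA and 3 Thr-AGT references, and the rises were those of 4 Gln-CTG and 3 Gln-TTG references, Leu-CAG-4-1 and Arg-ACG-1-1. Of 219 references, 9 rose and 9 fell, with 74 at an unadjusted p under 0.05. Asp-GTC-1-1 fell from 41460 ± 211 to 27650 ± 598 CPM (-0.58 ± 0.05, adjusted p = 0.000577). Asp-GTC-2-1 on chromosome 10 (91017959 to 91018030, minus strand, outside annotated genes) fell from 4298 ± 92.9 to 2774 ± 148 (-0.63 ± 0.07, 0.00099). Tyr-GTA-2-1 on chromosome 5 (31045427 to 31045515, plus strand, with an intron of 16 nt) fell from 9690.2 ± 361 to 6441 ± 284 (-0.59 ± 0.06, 0.00099). These 3 references passed in 15 of 15 alternatives. Gln-TTG-2-1 on chromosome 13 (21452639 to 21452710) rose from 81.5 ± 2.46 to 138 ± 20.6 (0.76 ± 0.15, 0.0183), and Leu-CAG-4-1, in an intron of Naaladl2 on chromosome 3 (24217189 to 24217271), rose from 343 ± 43.8 to 574 ± 111 (0.74 ± 0.17, 0.0376). Gln-TTG-4-1, on chromosome X (13725405 to 13725476), rose from 0.245 ± 0.0590 to 1.13 ± 0.373 CPM (0.0153) on 3 to 20 reads per library. Coordinates are of GRCm39. The number of references was 11 without 0Q replicate 1 (2 higher and 9 lower), 5 without 0Q replicate 3 (0 higher and 5 lower, with 44 at an unadjusted p under 0.05), 9 without 100Q replicate 1, 61 without 100Q replicate 2 and 9 without 100Q replicate 3. With the share of reads outside tRNA as a term in edgeR, chosen after seeing the data, it was 4 (0 higher and 4 lower, with 30 at an unadjusted p under 0.05), while DESeq2 called 16 higher and 25 lower without that term. Gln-TTG-2-1, Gln-TTG-4-1 and Leu-CAG-4-1 lost their calls without 0Q replicate 1 (adjusted p = 0.0722, 0.0722 and 0.135) and without 0Q replicate 3 (0.0778, 0.0658 and 0.126), Gln-TTG-2-1 and Leu-CAG-4-1 without 100Q replicate 3 (0.0856 and 0.120), and Leu-CAG-4-1 without 100Q replicate 1 (0.152).

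As groups, the mitochondrial tRNAs lay lower in queuine-fed cells, without a member that passed by itself. Their median log2 fold change was -0.49 over 22 families, and camera put them below the other tRNAs (adjusted p = 1.4e-09), but with an adjusted p = 0.375 with an estimated correlation. In edgeR 0 of the 22 passed, over all families or over the list alone, and 6 had an unadjusted p under 0.05, while DESeq2 called 2 lower and 0 higher. Their share of tRNA reads was 0.601% ± 0.121 in 0Q and 0.424% ± 0.0747 in 100Q (exact permutation p = 0.2), and the difference was -0.0820 and -0.126 points within barcodes 6 and 7. The share was 0.701%, 0.466% and 0.636% in 0Q replicates 1 to 3 and 0.384%, 0.510% and 0.378% in 100Q replicates 1 to 3, so that 100Q replicate 2 lay above 0Q replicate 2. Reads outside tRNA, chosen beforehand as a possible sign of RNA quality, also had a lower mean in 100Q, with 2.62% against 4.94%. RNA quality itself was not measured here. The 4 cytosolic queuosine tRNAs held 1 that rose, 2 that fell and 1 that did not pass, the same adjusted over the list alone, with a median of -0.17. Camera gave them an adjusted p of 0.423 (0.721 with an estimated correlation), and fry gave 0.103 for a change in 1 direction on balance and 0.000478 for changes in either direction, a mixed test that gave 0.00401 for the inosine tRNAs. Together they made up 12.4% ± 0.370 of cytosolic tRNA reads in 0Q and 10.3% ± 0.325 in 100Q (exact permutation p = 0.1), and -2.04 and -2.69 points within the barcodes. The 4 mitochondrial queuosine tRNAs had a median of -0.31 (adjusted p = 0.104, and 0.433 with an estimated correlation), with 0 that passed in edgeR over all families or over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2. Of the 8 inosine tRNAs, 0 passed in edgeR over all families, 6 had an unadjusted p under 0.05, and DESeq2 called 1 higher. Adjusted over the list alone 5 rose and 1 fell, with a median of 0.25 (camera 0.0663, and 0.433 with an estimated correlation). The list of 4 cytosolic tRNAs with guanosine but no queuosine at position 34 (Gly-GCC, Cys-GCA, Ser-GCT and Phe-GAA) had a median of -0.04 but a mean of 0.02 (camera 0.854), with 0 that passed in edgeR over all families or over the list alone, 1 at an unadjusted p under 0.05, and 0 by DESeq2.

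Reads on small RNAs other than tRNA were fewer in queuine-fed cells by their mean. They made up 4.94% ± 1.91 of reads in 0Q and 2.62% ± 0.626 in 100Q (exact permutation p = 0.2), and -0.925 and -3.77 points within barcodes 6 and 7. The 5S rRNA reference held 2.76% ± 1.09 against 1.29% ± 0.283 (0.2), a reference that matched no annotated transcript held 1.70% ± 0.696 against 1.01% ± 0.281 (0.3), and small nuclear RNAs held 0.481% ± 0.13 against 0.317% ± 0.0973 (0.2), each by the exact permutation test. Arg-TCT-4-1, the neuronal tRNA n-Tr20 and a marker of another cell type, had 2, 2 and 1 reads in 0Q and 1, 5 and 0 reads in 100Q, and the count of 0 in 100Q replicate 3 allows up to 0.238 CPM of tRNA reads. This floor covers counting error only.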

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

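The tests of explanations in this part were chosen only after the results were seen. Which base replaced guanosine 34 was not part of the planned comparisons, and several substitutions were at least 2 times as frequent with queuine as without, at 0.5% of reads or more and with groups that did not overlap. Positions are counted by canonical tRNA numbering, with the first anticodon base at 34. In cytosolic Tyr-GTA, G34C made up 0.724% of reads in 100Q against 0.0860% in 0Q, and its share of all mismatches at this base was 44.1% against 5.75%, while G34T made up 0.834% against 1.29%. In His-GTG, G34C made up 0.517% against 0.232% and G34T 0.975% against 0.197%. In Asn-GTT, G34T made up 1.99% against 0.586%, and in Asp-GTC, G34C made up 1.92% against 0.865%. In mt-Tyr-GTA, G34T made up 1.14% against 0.454%, and in mt-His-GTG 3.07% against 0.608%. In mt-Asp-GTC, G34A made up 0.525% against 0.0310%, G34C 3.96% against 1.35% and G34T 3.36% against 1.43%, on few reads. Each of these differences had an exact permutation p of 0.1, the smallest that this design allows. In mt-Asn-GTT, G34T made up 1.56% against 0.745%, with groups that overlapped (exact permutation p = 0.3). The share of cytosolic coverage that reached position 5, which no planned comparison used, was 68.9% in 100Q against 65.1% in 0Q.

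For the rise of mismatches at position 34, the bound was a log2 odds ratio of 0.77, an upper percentile of 264 other family positions with a mismatch share of 0.3% to 10% in 0Q. The highest of these other positions had 1.94, and 2 of them lay at or above 1.39, the median of the 8 queuosine families. Of the 8 families 6 lay above the bound, among them mt-Asn-GTT (0.91 ± 0.64), which did not pass its own test. This argues against a read-through difference between the pools that acts on all positions alike as the whole cause for the 8 as a set. The other positions were chosen by mismatch share and not by modification, so a difference that acts on modified bases stays open. The other 9 families with guanosine 34 had a median of 0.12, at most 0.49, which argues against more misreading of any guanosine there as the whole cause, but 18 references of 4 of them had a median of 0.43, against 0.91 for 15 queuosine references, so that it stays open for a part of the rise. For the mismatches of Asp-GTC and Tyr-GTA the higher value was 0.42, below that bound, so an effect of queuine and one of the pool cannot be told apart there, although deletions at this base rose in Asp-GTC (log2 odds ratio 1.48) and the mismatches of Tyr-GTA shifted from G34T toward G34C. Queuosine in place of guanosine, the difference the design names, stays a candidate explanation for all 8.

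Fewer stops and more mismatches at position 26 were weighed next. Less dimethylguanosine in 100Q would lower both, but the mismatch share had a higher mean in 26 of 26 families with fewer stops, which argues against it as the whole cause. A read-through difference between the library pools could lower stops and keep reads that carry a mismatch. Coverage reaching position 5 was 3.82 points higher in 100Q, and since every library of a group came from 1 pool, pool and queuine cannot be told apart here. An effect of queuine on these tRNAs stays open and untested.

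The fall of Asp-GTC and Tyr-GTA reads was weighed against counting effects. The log2 fold change nearest to 0 over 4 scalings was -0.44, which argues against scaling. Loss of reads with changes at position 34 would also lower His-GTG, which had more mismatches and deletions there but a log2 fold change of 0.46 ± 0.13, which argues against such a loss as the whole cause. The other 25 families with fewer stops at position 26 had a median of 0.17 (SD 0.17), which argues against a direct loss of Tyr-GTA reads with those stops. Asp-GTC was not among the families with fewer stops, so these values do not bear on its fall. CPM are relative, so they also cannot tell whether a gain of reads in those families lowered others. A difference between the pools in how well these tRNAs were captured was not tested, so an effect of queuine on their abundance is a hypothesis.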

How the results depend on the processing

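The share of non-tRNA reads as a term, the dispersion without a trend, and all alternatives for deletions, insertions and stops were chosen only after the results were seen. No result reversed among the 13 named families (195 comparisons: 166 with the call as in the report, 1 gained, 28 lost), 6 references (86: 72, 0 and 14), 8 position 34 values (110: 102, 1 and 7) and 46 named positions (528: 391, 0 and 137). Of 72 families, 6 of them called in the report, edgeR called 3 with a replicate block, 3 with the non-tRNA share as a term and 0 with barcode as a term, where 28 had an unadjusted p under 0.05, and DESeq2 without it called 9. His-GTG and Ser-CGA had an adjusted p of 0.128 with a replicate block and Tyr-GTA had 0.0502. Of 219 references, DESeq2 called 41 and edgeR 47 with barcode (18 of the 18 called in the report in each), 10 with a replicate block and 4 with the non-tRNA share. The fit with barcode leaves 1 residual degree of freedom, so its counts for families and references are uncertain. The replicate numbers do not pair the samples: deviations from the group mean correlated at -0.69 to -0.41 over 3 pairs of equal number, and at 0.71 to 0.74 over 2 pairs of equal barcode. At position 34 of the queuosine tRNAs, 5 of 8 passed with a replicate block, 4 with the non-tRNA share as a term and 3 with an unweighted mean over references, and with a coverage minimum of 1000 mt-Asn-GTT and mt-Asp-GTC gave no value. For all positions, limma on log2 odds called 82 mismatches, 65 deletions and 4 insertions, and 81, 105 and 7 passed with the non-tRNA share as a term, of which 67, 69 and 5 were called in the report. With no minimum share, 799 of 13175 mismatch positions passed, since more positions were tested. With an estimated correlation 0 of 5 gene lists passed in camera, against 1. Leaving out 1 library gave 3 (0Q replicate 1) to 36 (100Q replicate 2) families, 5 (0Q replicate 3) to 61 (100Q replicate 2) references, 4 to 5 position 34 values, 74 (100Q replicate 3) to 292 (0Q replicate 3) mismatch positions, 44 (100Q replicate 3) to 663 (0Q replicate 3) deletions, 2 (0Q replicate 2) to 13 (0Q replicate 3) insertions, 228 to 307 stops, and a mitochondrial difference of -0.244 to -0.127 points. The causes were not tested. Depth limits mt-Asn-GTT and mt-Asp-GTC, with 321 to 552 and 480 to 1077 reads at position 34.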

Other observations

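The tests of the sugar hypothesis and the counts of splits in this part were chosen only after the results were seen. Cytosolic Tyr-GTA and Asp-GTC, whose queuosine carries galactose or mannose in mammals, had smaller log2 odds ratios of a mismatch at position 34 than the queuosine families without a sugar, which prompted the hypothesis. Their mean log2 odds ratio of a mismatch at position 34 was 0.32, against 1.58 for the other 6 families, a difference of -1.25. Deletions at this base did not follow that split, with log2 odds ratios of 1.48 in Asp-GTC and 0.69 in Tyr-GTA against 0.41 to 1.49 in the other 6. The log2 contrast of Asp-GTC and Tyr-GTA over His-GTG and Asn-GTT in abundance was 1.02 ± 0.0789 in 0Q and 0.29 ± 0.225 in 100Q, a difference of -0.73 (exact permutation p = 0.1). Mitochondrial mt-Asp-GTC and mt-Tyr-GTA, which carry no sugar, had log2 fold changes of -0.51 and -0.33 without passing the test, but the median of all 22 mitochondrial families was -0.49, so these values do not bear on the sugar and the contrast covers the 4 cytosolic families alone. A sugar on queuosine may alter which changes reverse transcriptase makes at these tRNAs or how well they are captured. This stays a hypothesis found in the same data, and group and library pool cannot be told apart for it.

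Splitting the 6 libraries in other ways, 10 splits with the real one included, is too few for a share under 0.05. For families, 2 of 10 splits gave as many calls as the real 6, and the highest other gave 16, the split of 0Q replicates 1 and 3 with 100Q replicate 2 against the rest, which points to a structure of the samples. These 3 libraries came from both pools and held the highest mitochondrial shares of tRNA reads (0.701%, 0.636% and 0.510%), and with barcode as a term 0 families passed in edgeR, with 28 at an unadjusted p under 0.05. With that term the log2 fold changes of Asp-GTC and Tyr-GTA were -0.50 and -0.48 and those of Gln-TTG and Gln-CTG 0.63 and 0.52, and 47 references passed. A fit with barcode leaves 1 residual degree of freedom, so neither its count of families nor that of references is firm. For references 1 of 10 splits reached the real 18, with 6 the highest other. For position 34 of the queuosine tRNAs 1 of 10 reached the real 5, with 0 the highest other, and for mismatches at all positions 1 of 10 reached 143, with 0 the highest other. For deletions 1 of 10 reached 215, for insertions 1 of 10 reached 11 and for stops 1 of 10 reached 308, each with 0 the highest other. For gene lists 8 of 10 splits gave at least the real 1, with 3 the highest other.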
